A study of Homo sapiens with 156 samples.

How the data were processed

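Total RNA was sequenced from MV411, THP1 and NOMO1 cells, in 52 libraries per cell line. Per the labels' protocols, cells were plated a day before treatment, RNA was purified on RNeasy columns, and 150 of the libraries were pooled as paired-end libraries over 6 lanes, with no lane given for a library. Per the submitters' processing notes, the genome build was hg38 and the tools were Salmon 0.12.0 and DESeq2 without a version. How those tools turned reads into FPKM is not recorded. The authors deposited 1 table of FPKM values per cell line, with 59939 genes, and 1 table of log2 fold changes against DMSO per cell line without p-values. Whether strand was used is not recorded, so levels of antisense genes are uncertain.

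In units of 1000, column sums ran from 1331 to 3073 in MV411, 1263 to 2325 in THP1 and 1312 to 2052 in NOMO1, so the deposited FPKM values had not been scaled to equal sums. Gene names and coordinates come from the GENCODE 29 annotation of hg38, which held 56511 of the 59939 identifiers (94.3%). No pair of libraries held identical values. In MV411, 4 libraries, those of GSK862 and GSK477 at day 4, carry no replicate number of their own. The order of the MV411 columns leaves open whether the numbers of the day 6 libraries are exchanged within groups. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries.

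The files hold no counts. The depth was estimated from 9851 genes with 1 annotated transcript of 800 to 6000 bases, where FPKM times length should be whole multiples of 1 fragment. In MV411 77.1 to 89.6% of low values, up to 3 fragments, lay within 0.15 of a whole number, in THP1 75.8 to 86.1% and in NOMO1 57.7 to 89.8%, against 30% by chance. Genes with at least 3 transcripts gave 20.2 to 33.8%. The median scale was 74.0 M fragments in MV411, 71.9 M in THP1 and 77.4 M in NOMO1. The rule for choosing the unit was settled after values were seen. Tested on 8 simulated libraries, it found 0.997 to 1 of the simulated depth. Whole counts cannot be recovered for most genes, so no counting interval is given, and where the authors scaled by size factors the scale is not the library total.

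Each cell line was fitted on its own with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), the log2 values being computed from the deposited FPKM, with a mean for each of 26 groups and 26 residual degrees of freedom. The spread is therefore shared by all groups of 2. Genes with an FPKM of at least 1 in at least 2 libraries were tested, 22007 in MV411, 23226 in THP1 and 20763 in NOMO1. A gene silent in DMSO passed only where treated libraries reached that level. Shares of measured list members called higher were therefore partly fixed by this filter. Variances were moderated with a trend in the mean, and p-values adjusted by Benjamini and Hochberg over the genes of a contrast. The contrasts were each compound against DMSO of the same day, GSK032 against DAC at matched dose and day, GSK032 and DAC at 10000 nM against GSK477, the slope over 6 dose steps at day 4 times 5 steps, and the day 6 effect minus the day 1 effect at 400 nM. Samples, contrasts, thresholds, gene lists and the rule for naming genes were set before the data were examined. Contrasts of 10000 nM against 400 nM of a compound were added afterwards.

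The 24 gene lists were tested with camera at the preset inter-gene correlation of 0.01, and again with the correlation estimated from the residuals, adjusted over the lists of a contrast. All list members were found in the files except in the endogenous-retrovirus list (17 of 20) and the oxidative phosphorylation list (23 of 26). Of 720 planned list tests 457 were called, 210 of them also with an estimated correlation and 247 without it. The median, the mean and the test had the same sign in each called list. Counts of called members adjusted over the list alone were within 1 of the counts over all genes wherever both are named in the text, and are given where they differ. Of lists not described elsewhere, the oxidative phosphorylation and ribosomal protein lists were lower in THP1 with 400 nM GSK032 at day 4 (adjusted p = 0.0937 with an estimated correlation, and 0.0238).

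Genes were named by a rule. They had a symbol and a mean FPKM of at least 1 in the higher group. The rule took (a) genes called the same way in all lines with GSK032 or DAC at 400 nM, 10 higher and 5 lower by the smallest change over the lines, (b) the 3 largest changes in each direction per line, (c) the same for GSK862, GSK477 and the direct contrasts, (d) up to 4 called members of each list, or up to 2 uncalled members as values, (e) DNMT1, DNMT3A, DNMT3B and UHRF1, and (f) the 3 largest in each direction for trends and time. Of the genes it took, the text describes those whose call held under the alternatives, unless it says otherwise. List members called against their list, genes called in opposite directions by the compounds, those called after rescaling with GSK477 in THP1, and members of the fibroblast, epithelial and T-cell lists between doses of DAC were named after their values were seen. A Y-linked gene that the rule picked is not given. Levels of gene families with near-identical copies and of RNAs shorter than a fragment are uncertain.

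The fit was tested on simulated data. For GSK032 at 400 nM and day 4 in MV411, over 22007 genes, 44% of genes raised 2-fold and 20% of those lowered 2-fold were called, 92% and 80% at 4-fold, 88% and 84% at 8-fold, and 96% and 84% at 16-fold, with 3 wrong calls among 21787 unchanged genes. For the same contrast in THP1 the shares were 24% and 20% at 2-fold and 88% and 92% at 4-fold, and in NOMO1 32% and 28%, and 100% and 84%. A raised list was called in each, and 0 of 23 unchanged lists were called. Changed genes were drawn only from those with at least 1 FPKM in DMSO in these contrasts. Genes near 0 there, such as PNMA5, were thus not simulated as changed. The noise of a gene had the same spread in every group, so the few wrong calls do not test that assumption of the fit. It was also drawn independently for each gene. The simulated lists thus held no inter-gene correlation and cannot show how it affects the list p-values. In 20 simulated draws of unchanged groups against the real DMSO libraries, no overlap of called genes arose.

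Whether replicate numbers pair libraries across groups was checked by correlating the differences between the libraries numbered 1 and 2. The median correlation between groups was 0.08 in MV411 (−0.2 to 0.42), 0.08 in THP1 (−0.01 to 0.22) and 0.09 in NOMO1 (−0.12 to 0.23). It exceeded 0.1 in 36.6, 28.6 and 34.5% of the pairs of groups. The numbers were therefore not used as pairs in the main fit, but a weak difference shared by libraries of the same number is not excluded. The alternatives were pseudocounts of 0.1 and 1, no filter, rescaling each library to the same sum (TPM rescale), a replicate block, an estimated list correlation and leaving out each library in turn. With 1 library left in a group, the fit assumes that it varies like the other groups. Groups of 2 were not tested for outlying samples or other splits. The authors' fold changes were compared with the limma ones but not used. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 handled tables and figures.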

Results

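RNA was sequenced from 3 human acute myeloid leukemia cell lines, MV411, THP1 and NOMO1, all of which carry a rearranged KMT2A gene. The study concerns inhibitors of DNMT1, the enzyme that copies DNA methylation onto newly made DNA. GSK032 (GSK3685032) was compared with decitabine (DAC), a cytosine analog that enters DNA and traps DNMT1, with a pair of further compounds, GSK862 (GSK3484862) and GSK477 (GSK3510477), and with the solvent DMSO. Each cell line had 26 groups of 2 libraries, 156 libraries in all. GSK032 and DAC were given at 400 nM for 1, 2, 4 and 6 days and at 3.2, 16, 80, 400, 2000 and 10000 nM for 4 days. GSK862 at 1000 nM and GSK477 at 10000 nM were sampled on days 2 and 4, and DMSO on days 1, 2, 4 and 6. The deposited values are FPKM for 59939 genes, without read counts. From low values of genes with 1 annotated transcript, the scale of a library corresponded to 44.0 to 96.0 M fragments in MV411, 37.1 to 103 M in THP1 and 55.4 to 151 M in NOMO1. That scale is the authors' and need not be the library total.

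Fold changes are limma estimates on the log2(FPKM + 0.5) scale with their standard error, which understates changes of genes near 0. Levels are mean FPKM ± SD (n = 2 libraries per group), treated before control. A gene was called when its adjusted p was below 0.05 and its log2 fold change at least 1 in size. Gene lists were fixed in advance and tested with camera, a test of a list against all other genes. Their counts cover only members with at least 1 FPKM in at least 2 libraries of a line. A gene silent in DMSO enters only if treated libraries raise it, so counts of higher members are partly fixed by this filter. Where a list passed with the preset correlation only, its adjusted p with an estimated correlation follows, and all other list calls given here held with both. The cell lines were fitted apart, and no difference between them was tested.

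The first question was which genes respond to GSK032 at 400 nM after 4 days. Among the genes that rose furthest in all 3 lines were germline genes such as MAGEA4 and genes of other kinds such as PNMA5 and ZNF595. PNMA5, a gene of the paraneoplastic Ma antigen family on the X chromosome (ENSG00000198883, hg38, 152988824 to 152994127), rose by 6.93 ± 0.20 (87.2 ± 7.21 against 0.218 ± 0.0362 FPKM) in MV411. In THP1 it rose by 5.24 ± 0.29 (21.9 ± 0.507 against 0.0933 ± 0.000256 FPKM) and in NOMO1 by 4.95 ± 0.21 (24.8 ± 1.18 against 0.36 ± 0.374 FPKM). MAGEA4, a melanoma antigen gene on the same chromosome (ENSG00000147381, 151912509 to 151925170), rose by 6.49 ± 0.23 (148 ± 13.4 against 1.15 ± 0.0164 FPKM), 5.23 ± 0.23 (57.2 ± 0.805 against 1.07 ± 0.437 FPKM) and 4.53 ± 0.22 (16.9 ± 0.408 against 0.262 ± 0.174 FPKM). ZNF595, a zinc finger gene at the end of chromosome 4 (ENSG00000272602, 53285 to 88211), rose by 6.12 ± 0.18, 4.41 ± 0.24 and 5.33 ± 0.17. TKTL1, a transketolase-like gene of the testis (ENSG00000007350), rose by 7.96 ± 0.32 in MV411. In each line both treated libraries stood above both DMSO libraries for PNMA5 and MAGEA4. Of the germline list, 37 of 42 measured members were called higher in MV411 (adjusted p = 2.1e-41), 11 of 34 in THP1 (adjusted p = 4.35e-13) and 11 of 36 in NOMO1 (adjusted p = 1.25e-14). MAGEA4 belongs to a family of near-identical copies, and how the authors' quantification shared reads among them is not given.

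In MV411 the response to GSK032 reached beyond germline genes, to immune, monocytic and cell-cycle genes. The interferon-induced gene IFI27 (ENSG00000165949, chromosome 14, 94104836 to 94116698) rose by 4.83 ± 0.42 (48.5 ± 0.629 against 1.25 ± 0.46 FPKM) and IFI6 by 2.55 ± 0.23 (53.3 ± 6.26 against 8.8 ± 2.29 FPKM), among 26 of 45 interferon-list members called higher (adjusted p = 1.36e-18, and adjusted p = 0.057 with an estimated correlation). The HLA class II genes HLA-DPA1 and HLA-DRA, which present antigen to T cells, rose by 3.65 ± 0.24 (26.1 ± 0.981 against 1.63 ± 0.124 FPKM) and 2.56 ± 0.19 (98.7 ± 2.67 against 16.3 ± 0.297 FPKM). Of the antigen-presentation list, 14 of 25 were called (adjusted p = 1.85e-11, and adjusted p = 0.0677 with an estimated correlation). Lysozyme (LYZ), a product of monocytes, rose by 2.08 ± 0.17 (3130 ± 191 against 743 ± 93.6 FPKM), and 7 of 23 monocyte genes were called higher (adjusted p = 5.74e-06, and adjusted p = 0.1 with an estimated correlation). The cyclin-dependent kinase CDK1 fell by 1.39 ± 0.10 (39 ± 1.82 against 103 ± 5.82 FPKM) with 25 of 30 mitosis genes (adjusted p = 1.43e-29). RRM2, a subunit of ribonucleotide reductase, had a change of −1.58 ± 0.13, with 23 of 30 S-phase genes called lower (adjusted p = 4.01e-26). Replication-linked histone genes had a median change of −1.46, with 14 of 16 called lower (adjusted p = 9.93e-12, and adjusted p = 0.1 with an estimated correlation). TERT, the catalytic subunit of telomerase, fell by 2.39 ± 0.22 and PHGDH, the first enzyme of serine synthesis, had a change of −2.01 ± 0.19. The serine enzyme stood among 10 of 24 stress-response members called lower, with HMOX1 higher (adjusted p = 5.74e-06, and adjusted p = 0.1 with an estimated correlation). The cholesterol and lipid list was lower, with 7 of 23 members called (adjusted p = 9.73e-08, and adjusted p = 0.224 with an estimated correlation). ERV3-1, a gene derived from a retrovirus, rose by 1.58 ± 0.14, among 3 of 7 endogenous-retrovirus genes called, or 4 when adjusted over the list alone (adjusted p = 0.00892, and adjusted p = 0.1 with an estimated correlation). The imprinted growth inhibitor CDKN1C rose by 2.27 ± 0.24, among 3 of 17 imprinted genes called (adjusted p = 0.00351, and adjusted p = 0.0677 with an estimated correlation). The B-cell list, with 3 of 7 called, included the kinase gene BLK at 2.39 ± 0.19 (adjusted p = 0.0021, and adjusted p = 0.0778 with an estimated correlation).

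THP1 and NOMO1 responded to 400 nM GSK032 with fewer called genes, and in partly different gene groups. In THP1, IFI27 rose by 4.58 ± 0.35 (42.9 ± 1.2 against 1.31 ± 0.117 FPKM) and the antiviral gene MX1 by 1.68 ± 0.10 (19.5 ± 0.798 against 5.78 ± 0.862 FPKM). There 14 of 45 interferon genes were called (adjusted p = 1.28e-24). SCD, which makes monounsaturated fatty acids (ENSG00000099194, chromosome 10, 100347124 to 100364834), fell by 1.21 ± 0.09 (40.7 ± 0.622 against 94.5 ± 3.65 FPKM) as the 1 called member of a cholesterol and lipid list that was lower as a whole (adjusted p = 6.78e-17). The S-phase list was also lower, with 0 members called by limma and a median of −0.65 (adjusted p = 7.4e-26). In NOMO1, KIT and FLT3, receptor kinases of blood progenitors, had changes of −1.71 ± 0.19 (6.26 ± 0.421 against 21.6 ± 2.35 FPKM) and −1.28 ± 0.10 (7.76 ± 0.947 against 19.5 ± 0.0593 FPKM). They were the 2 called members of the KMT2A and stem-cell list (adjusted p = 3.73e-08). GATA1, the regulator of red-cell and platelet precursors, and the platelet integrin ITGA2B rose by 3.34 ± 0.14 (6.91 ± 0.0783 against 0.231 ± 0.032 FPKM) and 2.78 ± 0.26 (14.5 ± 0.462 against 1.69 ± 0.218 FPKM). They were among 5 of 10 erythroid and megakaryocyte genes called (adjusted p = 9.73e-07). The T-cell receptor gene CD3D rose by 1.44 ± 0.25 (31.7 ± 3.43 against 11.4 ± 1.6 FPKM), among 3 of 10 T-cell genes called (adjusted p = 0.00692). The monocyte genes CD14 and S100A12 rose by 1.88 ± 0.24 and 1.79 ± 0.16, with 3 of 30 monocyte genes called (adjusted p = 1.21e-06, and adjusted p = 0.101 with an estimated correlation). The interferon list did not pass in NOMO1, with LGALS3BP and IFITM1 called higher and CXCL10 lower of 43 members. The IFITM1 call ended without the second GSK032 library, at 1.25.

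The target itself was not called. DNMT1 RNA (ENSG00000130816) had a change of −0.42 ± 0.09 in MV411, −0.27 ± 0.07 in THP1 and −0.06 ± 0.11 in NOMO1. UHRF1, which brings DNMT1 to replicated DNA, had changes of −0.94 ± 0.14, −0.44 ± 0.09 and −0.03 ± 0.07. In all, limma called 1442 genes higher and 607 lower of 22007 tested in MV411, 450 and 78 of 23226 in THP1, and 530 and 78 of 20763 in NOMO1. Of 17787 genes tested in every line, 74 were called higher and 2 lower in all 3. The 1 of the 2 with a symbol was ONECUT2, a developmental transcription factor gene, at −1.02 in MV411, −1 in THP1 and −1.29 in NOMO1. In MV411 its change was −0.72 without the second DMSO library and −0.95 without the second GSK032 library. In THP1 it was −0.86 without the first DMSO library and −0.92 without the first GSK032 library, so that both calls ended. Rescaling every MV411 library to the same sum moved the median gene by 0.21 and the split to 1657 higher and 213 lower.

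**Figure D1:**
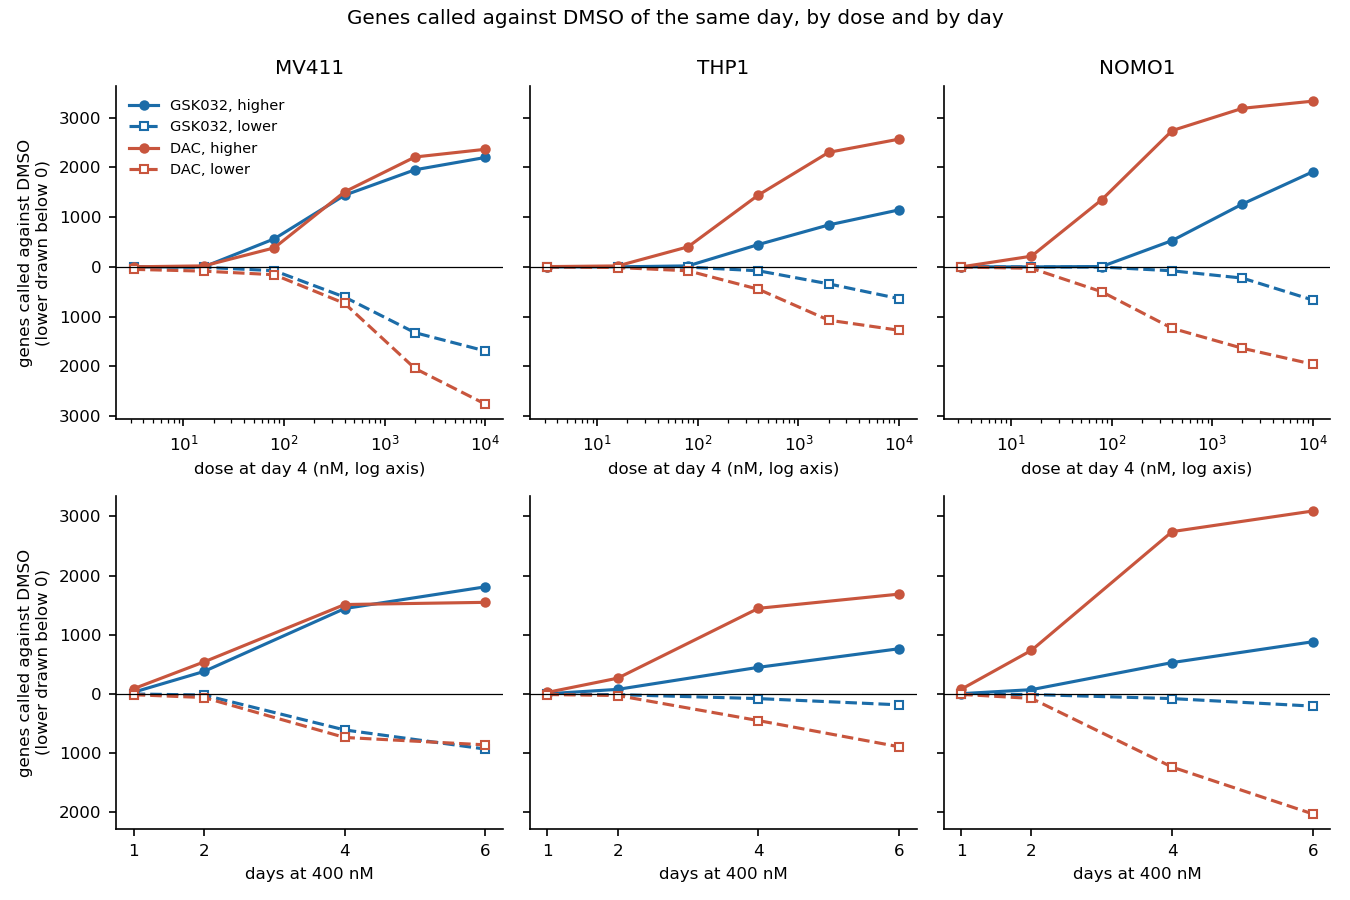
Number of genes called higher (filled circles) and lower (open squares, drawn below 0) than DMSO of the same day, against dose at day 4 on a log axis in nM (top) and against days at 400 nM (bottom), for GSK032 and DAC in each cell line. In NOMO1 DAC called 2741 genes higher at 400 nM on day 4 and GSK032 530, while in MV411 the counts were 1510 and 1442.

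The next question was what DAC does at the same dose and day. PNMA5 and germline genes rose in every line, and genes of fatty acid and sterol synthesis fell. PNMA5 rose by 5.88 ± 0.20 (41.9 ± 3.12 against 0.218 ± 0.0362 FPKM) in MV411, 5.33 ± 0.29 (23.3 ± 0.53 against 0.0933 ± 0.000256 FPKM) in THP1 and 5.14 ± 0.21 (28.4 ± 0.806 against 0.36 ± 0.374 FPKM) in NOMO1. Of the germline list, 31 of 42 were called higher in MV411 (adjusted p = 1.23e-32), with TEX15 lower. The count was 23 of 34 in THP1 (adjusted p = 2.17e-20), with TEX15 again lower, and 27 of 36 in NOMO1 (adjusted p = 4.21e-14). STAB1, a scavenger receptor gene (ENSG00000010327, chromosome 3), rose by 5.58 ± 0.29 (45.8 ± 1.68 against 0.468 ± 0.0767 FPKM), 4.09 ± 0.24 and 5.30 ± 0.22. SCD had changes of −3.52 ± 0.24 (11.9 ± 1.11 against 142 ± 12.7 FPKM), −2.47 ± 0.09 (16.6 ± 1.19 against 94.5 ± 3.65 FPKM) and −2.57 ± 0.17 (22.8 ± 1.72 against 138 ± 0.339 FPKM). Fatty acid synthase (FASN) had changes of −2.25 ± 0.20, −2.05 ± 0.17 and −2.04 ± 0.18. Of the cholesterol and lipid list, 21 of 23 members were called lower in MV411 (adjusted p = 5.28e-19, and adjusted p = 0.0567 with an estimated correlation), 21 of 23 in THP1 (adjusted p = 1.31e-23) and 18 of 23 in NOMO1 (adjusted p = 1.74e-11). The small nucleolar RNA gene SNORA81 is listed at 0 FPKM in DMSO of all 3 lines and at 20.5 ± 9.22, 16.9 ± 0.146 and 39.4 ± 16.6 FPKM with DAC. It is shorter than a usual fragment, so these levels are uncertain.

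The count of interferon genes was highest in THP1. IFI27 went from 1.31 ± 0.117 to 471 ± 18.7 FPKM there (8.02 ± 0.35), and IFI44L rose by 4.84 ± 0.21 (35.5 ± 2.56 against 0.762 ± 0.141 FPKM). There 41 of 45 interferon genes were called (adjusted p = 1.24e-47). In NOMO1 the count was 17 of 43, with MX2 lower (adjusted p = 0.000156) and in MV411 6 of 45 (adjusted p = 2.1e-06, and adjusted p = 0.215 with an estimated correlation). The calgranulin S100A9, abundant in monocytes, rose by 2.74 ± 0.13 (686 ± 30.5 against 102 ± 7.75 FPKM) in THP1 with 13 of 25 monocyte genes (adjusted p = 6.89e-13). BCL2, which blocks apoptosis, fell by 1.41 ± 0.07 (20.7 ± 0.531 against 55.9 ± 5.06 FPKM). Targets of p53 were higher in THP1, with 8 of 32 called (adjusted p = 0.000176), GDF15 at 2.28 ± 0.22 among them. The apoptosis list was higher in THP1, with 3 of 21 members called higher and BCL2 lower, among them the BH3-only gene BMF at 2.21 ± 0.14 (adjusted p = 0.0149). That list did not pass after rescaling every library to the same sum (adjusted p = 0.13).

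DAC called the most genes in NOMO1, in groups from several lineages. H19, an imprinted long RNA (ENSG00000130600, chromosome 11, 1995176 to 2001470), rose by 7.43 ± 0.34 (103 ± 3.02 against 0.0987 ± 0.0224 FPKM). It was among 9 of 19 imprinted genes called, or 10 when adjusted over the list alone (adjusted p = 3.37e-06). CD3D rose by 3.70 ± 0.25 (154 ± 8.98 against 11.4 ± 1.6 FPKM) with 9 of 10 measured T-cell genes, of 16 in the list (adjusted p = 1.78e-08). The matrix protein SPARC (ENSG00000113140) rose by 4.75 ± 0.35 (18.3 ± 2.51 against 0.203 ± 0.167 FPKM) with 11 of 11 measured fibroblast genes, of 14 in the list (adjusted p = 1.56e-07). The other members, COL3A1, FAP and POSTN, were too low to be tested, so this count was partly fixed by the filter. The tight-junction gene CLDN7 rose by 3.52 ± 0.20 with 8 of 12 epithelial genes (adjusted p = 1.56e-05). The cytokine IL1B rose by 4.45 ± 0.24 (211 ± 35.1 against 9.12 ± 0.8 FPKM) with 23 of 27 NF-kB and inflammation genes (adjusted p = 7.33e-13, and adjusted p = 0.0524 with an estimated correlation). ITGA2B rose by 5.18 ± 0.26 with 8 of 10 erythroid and megakaryocyte genes, NFE2 being lower (adjusted p = 0.000362). DEFA4, a defensin of neutrophil precursors (ENSG00000164821, chromosome 8, 6935822 to 6938338), fell by 4.12 ± 0.15 (27.7 ± 1.08 against 489 ± 3.23 FPKM). FLT3 fell by 2.97 ± 0.10 with 6 of 22 KMT2A and stem-cell genes (adjusted p = 1.38e-06). The oxidative phosphorylation list was lower with 5 of 23 called (adjusted p = 7.97e-09), the ribosomal protein list with 9 of 28 (adjusted p = 1.47e-12, and adjusted p = 0.0634 with an estimated correlation) and the histone list with 10 of 16 (adjusted p = 2.09e-06, and adjusted p = 0.0835 with an estimated correlation).

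In MV411 the mitosis and S-phase lists were lower with DAC as they were with GSK032. DAC had 27 of 30 mitosis genes (adjusted p = 3.99e-27) and 24 of 30 S-phase genes (adjusted p = 4.68e-24) called lower. UHRF1 (ENSG00000276043) fell by 1.51 ± 0.14 there (50.1 ± 5.76 against 143 ± 7.71 FPKM), and CDCA7, which recruits a chromatin remodeller for methylation, had a change of −2.15 ± 0.10. They were the 2 methylation-machinery members called lower of 19, with DNMT3L higher (adjusted p = 0.00431, and adjusted p = 0.131 with an estimated correlation). DNMT1 was not called, at −0.69 ± 0.09, −0.64 ± 0.07 and −0.40 ± 0.11 in MV411, THP1 and NOMO1. The nucleoside metabolism list was lower with 2 of 15 called in THP1 (adjusted p = 0.000708). DAC called 1510 genes higher and 734 lower in MV411, 1446 and 449 in THP1, and 2741 and 1234 in NOMO1. In all 3 lines, 70 genes were called lower. Of genes with a symbol and a mean FPKM of at least 1 in the higher group, 334 were called higher and 68 lower in all 3. After rescaling to equal sums, which moved the median THP1 gene by −0.27, the split was 771 higher and 1296 lower in THP1 and 969 and 816 in MV411.

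**Figure D2:**
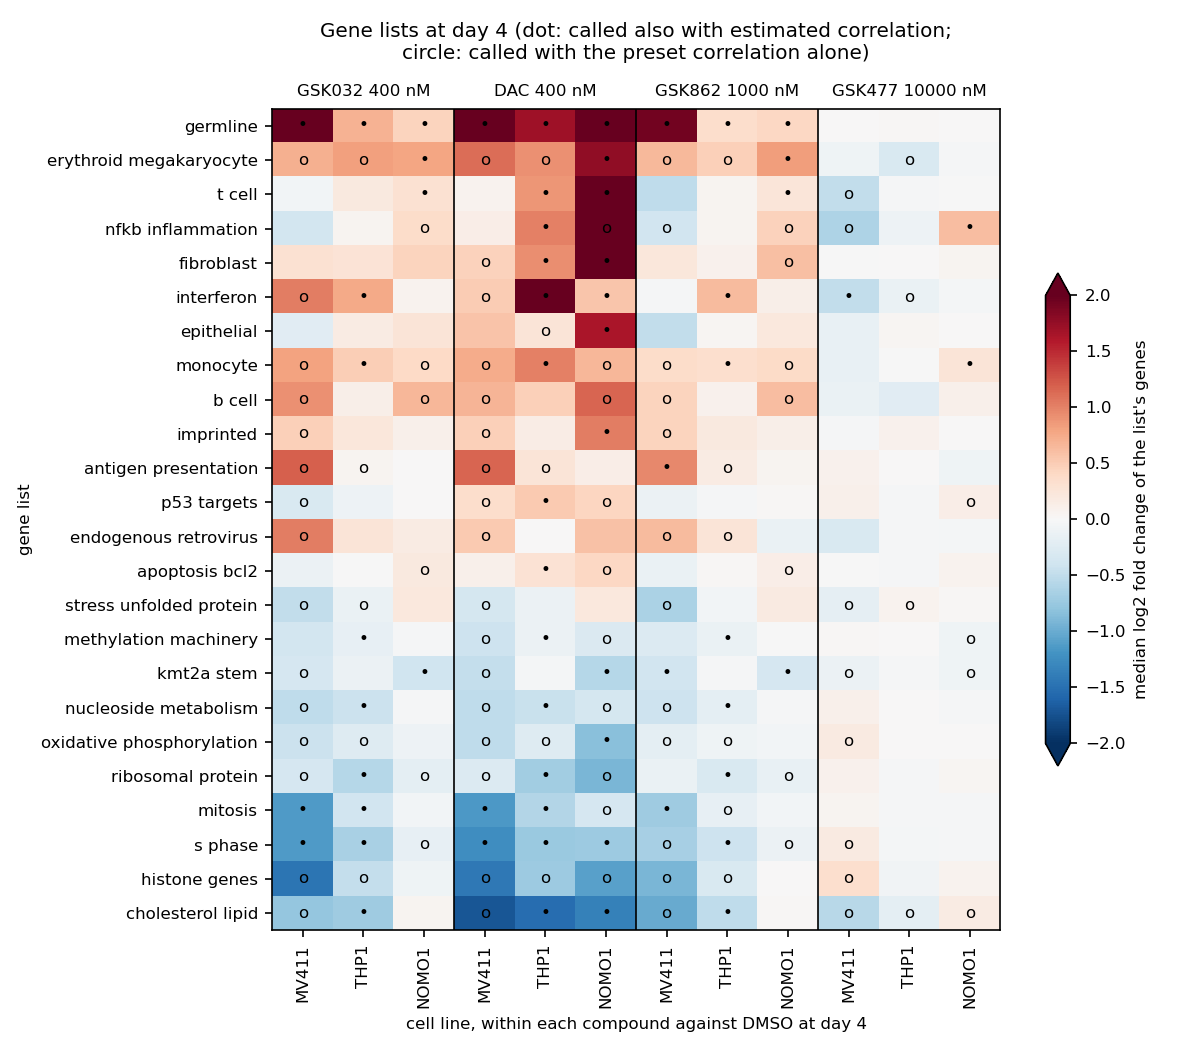
Median log2 fold change over the measured members of each of the 24 gene lists (color scale), for each compound against DMSO at day 4 in each cell line, with a dot where camera called the list with preset and estimated correlation and a circle where with the preset alone. The cholesterol and lipid list was at −1.71 with DAC in MV411, and the germline list at 2.68 with GSK032 in MV411.

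GSK032 and DAC were then compared with each other at 400 nM and day 4, where positive values are higher with GSK032. PNMA5 and MAGEA4 did not pass the test in THP1 and NOMO1, where many germline and interferon genes were higher with DAC, and lipid synthesis genes were higher with GSK032 in each line. The difference for PNMA5 was −0.09 in THP1 (95% interval −0.68 to 0.50) and −0.19 in NOMO1 (−0.63 to 0.24), neither called, and for MAGEA4 −0.05 (−0.52 to 0.42) and −0.25 (−0.70 to 0.21). In MV411, PNMA5 was higher with GSK032 by 1.05 ± 0.20 (0.63 to 1.47). Over the germline list, 18 of 34 members were lower with GSK032 in THP1 (adjusted p = 4.27e-17) and 19 of 36 in NOMO1, with GTSF1 higher (adjusted p = 5.77e-11). DAZL, an RNA-binding protein of germ cells, was at 0.113 ± 0.0415 against 21.1 ± 1.92 FPKM in NOMO1 (−5.14 ± 0.17). In MV411 it was higher with GSK032 by 1.24 ± 0.19 (20.3 ± 2.67 against 8.24 ± 0.302 FPKM), the 1 of 42 called, with the list higher as well (adjusted p = 2.1e-11, and adjusted p = 0.0839 with an estimated correlation).

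Interferon genes were lower with GSK032 than with DAC in THP1 (35 of 45 called, adjusted p = 2.03e-53) and NOMO1 (14 of 43, adjusted p = 0.000135), and higher in MV411 (12 of 45, adjusted p = 1.08e-15, and adjusted p = 0.0839 with an estimated correlation). IFI27 in THP1 differed by −3.44 ± 0.35 (42.9 ± 1.2 against 471 ± 18.7 FPKM), and MX1 in MV411 by 1.62 ± 0.23 (20.9 ± 0.638 against 6.51 ± 0.913 FPKM). Targets of p53 were lower with GSK032 in MV411 (6 of 34, adjusted p = 1.82e-25). There PLK2, a kinase induced by p53, differed by −2.03 ± 0.17 (12.6 ± 0.217 against 53.2 ± 3.64 FPKM) and the cell-cycle inhibitor CDKN1A by −1.44 ± 0.20. Lipid synthesis genes were higher with GSK032 in each line. SCD differed by 2.23 ± 0.24 (60.6 ± 26.3 against 11.9 ± 1.11 FPKM) in MV411 and 2.62 ± 0.17 (143 ± 7.67 against 22.8 ± 1.72 FPKM) in NOMO1. The desaturase FADS2 differed by 1.66 ± 0.16 (59.4 ± 7.99 against 18.3 ± 1.31 FPKM) in THP1. The lipid list members called were 9 of 23 in MV411 (adjusted p = 3.34e-23, and adjusted p = 0.0821 with an estimated correlation), 9 of 23 in THP1 (adjusted p = 2.86e-19) and 18 of 23 in NOMO1 (adjusted p = 2.22e-14). In NOMO1, DEFA4 was at 755 ± 31.9 against 27.7 ± 1.08 FPKM (4.74 ± 0.15), H19 at 2.04 ± 0.112 against 103 ± 3.02 FPKM (−5.35 ± 0.34) and IL1B at 22.9 ± 0.865 against 211 ± 35.1 FPKM (−3.17 ± 0.24). The fibroblast list was lower with GSK032 in NOMO1, with 10 of 11 called (adjusted p = 5.88e-08). DNMT1 was not called, with differences of 0.27 (0.08 to 0.46), 0.37 (0.22 to 0.53) and 0.34 (0.11 to 0.57) in MV411, THP1 and NOMO1. In all, 150 genes were higher and 271 lower with GSK032 in MV411, 358 and 694 in THP1, and 726 and 2021 in NOMO1. After rescaling to equal sums, which moved the median gene by 0.31 in MV411 and 0.24 in THP1, the split turned to 442 higher and 142 lower in MV411 and 579 and 336 in THP1.

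GSK862 was sampled at 1000 nM, so its values stand beside those of GSK032 at 400 nM without a test. Germline genes rose with it in each line, with antigen-presentation genes in MV411 and erythroid and megakaryocyte genes in NOMO1. MAGEA4 rose by 6.44 ± 0.23 (143 ± 6.48 against 1.15 ± 0.0164 FPKM) in MV411, 5.26 ± 0.23 (58.5 ± 10 against 1.07 ± 0.437 FPKM) in THP1 and 4.34 ± 0.22 in NOMO1. TKTL1 rose by 8.00 ± 0.32 (294 ± 24.3 against 0.645 ± 0.0535 FPKM) in MV411. The germline genes called were 30 of 42 (adjusted p = 4.18e-43), 6 of 34 (adjusted p = 1e-09) and 8 of 36 (adjusted p = 2.89e-12). HLA-DPA1 rose by 3.31 ± 0.24 and LYZ by 2.28 ± 0.17 (3610 ± 259 against 743 ± 93.6 FPKM) in MV411 and IFI27 by 4.21 ± 0.35 (33.2 ± 5.09 against 1.31 ± 0.117 FPKM) in THP1. In NOMO1, GATA1 rose by 3.22 ± 0.14 and ITGA2B by 2.76 ± 0.26, and KIT fell by 1.62 ± 0.19. The lists called higher included antigen presentation in MV411 (12 of 25, adjusted p = 5.22e-14), interferon in THP1 (11 of 45, adjusted p = 1.32e-29) and erythroid and megakaryocyte genes in NOMO1 (5 of 10, adjusted p = 9.32e-08). In MV411, where the interferon list did not pass (adjusted p = 0.756), IFIT2 had a change of −1.45 ± 0.24 and the chemokine CCL5 of −2.49 ± 0.28. The cholesterol and lipid list was lower with 12 of 23 called (adjusted p = 7.22e-13, and adjusted p = 0.113 with an estimated correlation). GSK862 called 924 genes higher and 257 lower in MV411, 271 and 33 in THP1, and 501 and 97 in NOMO1.

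GSK477 at 10000 nM called fewer genes at day 4 than GSK032 or DAC at 400 nM and GSK862 at 1000 nM, and the germline list did not pass in MV411 (adjusted p = 0.44), THP1 (adjusted p = 0.272) or NOMO1 (adjusted p = 0.775). In MV411, 7 genes were called higher and 98 lower, and the germline list had 0 of 42 members called by limma and a median of 0.00. The interferon-induced genes IFIT2 and OAS1 had changes of −2.34 ± 0.24 (0.0528 ± 0.0184 against 2.34 ± 0.797 FPKM) and −2.29 ± 0.27 (0.378 ± 0.173 against 3.81 ± 0.953 FPKM). They were among 10 of 45 interferon genes called lower (adjusted p = 3.51e-34). CCL5 fell by 2.00 ± 0.28 (8.26 ± 0.28 against 34.6 ± 4.39 FPKM) with 4 of 19 NF-kB and inflammation genes (adjusted p = 3.74e-08, and adjusted p = 0.203 with an estimated correlation). PIR, an iron-binding nuclear protein gene, and NQO1, a quinone reductase of the oxidative stress response, rose by 1.74 ± 0.19 and 1.64 ± 0.25. In NOMO1, 36 genes were called higher and 8 lower, and CLEC7A, a fungal glucan receptor of myeloid cells, rose by 1.13 ± 0.16 (12.2 ± 0.138 against 5.29 ± 0.279 FPKM). There 7 of 27 NF-kB and inflammation genes were called higher, or 8 when adjusted over the list alone (adjusted p = 2.23e-28). The interferon list did not pass in NOMO1 (adjusted p = 0.396) and was lower in THP1 with a median of −0.14 (adjusted p = 0.000192, and adjusted p = 0.731 with an estimated correlation). In THP1, 2 genes were called higher and 7 lower. After rescaling to equal sums limma called 4 higher and 0 lower there (1012 at an unadjusted p under 0.05), namely FTL, PIR, NQO1 and a gene without a symbol, the last being the 1 gene shared with the 9. FABP4, a fatty acid carrier, was among the higher at 1.03 in THP1, and its call ended without any 1 of the 4 libraries. It was at 0.93 without the first DMSO library, 0.95 without the first GSK477 library, 1.13 without the second DMSO library (adjusted p = 0.0569) and 1.11 without the second GSK477 library (adjusted p = 0.0747). The THP1 total of 9 rose without the first DMSO day 4 library, where most calls were lower. It also rose without the first GSK477 library, where most calls were higher, so the direction of these few calls rests on single libraries. The NOMO1 total of 44 became 99 without the first GSK477 library and 18 without the second DMSO day 4 library.

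At 10000 nM and day 4, GSK032 was compared directly with GSK477. IFI27 was at 338 ± 27.4 against 1.07 ± 0.629 FPKM in MV411 (7.81 ± 0.42). PNMA5 differed by 6.00 ± 0.29 (40.5 ± 1.12 against 0.138 ± 0.00366 FPKM) in THP1 and ZNF595 by 7.70 ± 0.17 (121 ± 10.6 against 0.0833 ± 0.0432 FPKM) in NOMO1. Germline genes called higher with GSK032 were 40 of 42 in MV411 (adjusted p = 2.7e-33), 23 of 34 in THP1 with GTSF1 lower (adjusted p = 6.25e-22) and 28 of 36 in NOMO1 (adjusted p = 3.94e-24). Interferon genes were higher in MV411 (43 of 45, adjusted p = 1.43e-36) and THP1 (34 of 45, adjusted p = 5.11e-36). In MV411 the interferon list was itself lower with GSK477 than with DMSO, so the difference there includes that fall. S-phase genes were lower in MV411 (30 of 30, adjusted p = 8.43e-27) and THP1 (19 of 30, adjusted p = 2.8e-24). DNMT1 differed by −0.81 (95% interval −1 to −0.62) in MV411, −0.41 (−0.56 to −0.26) in THP1 and −0.04 (−0.26 to 0.19) in NOMO1 and was not called. The totals were 2713 higher and 2018 lower in MV411, 1216 and 624 in THP1, and 1715 and 519 in NOMO1. Rescaling to equal sums moved the median gene by 0.12 in MV411, −0.17 in THP1 and 0.08 in NOMO1. The splits became 2676 higher and 1323 lower, 825 and 1206, and 1629 and 294.

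The dose titration asked which genes follow the dose over 6 steps at day 4, with the trend given over the full range and levels at 10000 nM against 3.2 nM. With GSK032, interferon and germline genes climbed in MV411, where IFI27 had a trend of 9.88 ± 0.35 (338 ± 27.4 against 1.15 ± 0.56 FPKM), MX1 of 6.06 ± 0.20 (96.6 ± 1.27 against 3.95 ± 0.202 FPKM) and DAZL of 8.63 ± 0.16 (68.9 ± 7.05 against 0.025 ± 0.0288 FPKM). In that line 43 of 45 interferon genes (adjusted p = 5.48e-34) and 39 of 42 germline genes rose with dose (adjusted p = 7.56e-33), and 30 of 30 mitosis genes fell (adjusted p = 4.22e-28). In THP1, IFI27 had a trend of 7.01 ± 0.30 (173 ± 22.8 against 1.75 ± 0.272 FPKM) and 34 of 45 interferon genes rose (adjusted p = 1.49e-32). In NOMO1, MAGEA4 had a trend of 8.63 ± 0.19 (81.2 ± 5.96 against 0.0943 ± 0.0786 FPKM) and IL1B of 4.25 ± 0.20 (318 ± 117 against 13.8 ± 0.102 FPKM). KIT had a downward trend of 4.32 ± 0.16 there (0.893 ± 0.472 against 20.6 ± 2.03 FPKM), and 9 of 22 KMT2A and stem-cell genes fell (adjusted p = 3.77e-09). The GSK032 trend was called for 2563 genes higher and 2095 lower in MV411, 1380 and 922 in THP1, and 1981 and 748 in NOMO1. The THP1 libraries of 16 and 80 nM numbered 1 are in doubt, since the authors' deposited fold changes do not follow them. Without both of them, chosen after seeing the data, the THP1 total was 2348.

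With DAC, matrix genes followed the dose in THP1 and NOMO1. SPARC had trends of 8.29 ± 0.17 (177 ± 5.67 against 0.561 ± 0.0405 FPKM) and 7.62 ± 0.29 (85.8 ± 1.43 against 0.181 ± 0.0286 FPKM). There 9 of 10 (adjusted p = 1.31e-08) and 11 of 11 fibroblast genes were called (adjusted p = 4.69e-07). The gelatinase MMP9 had a trend of 7.37 ± 0.31 (507 ± 61.2 against 2.81 ± 0.249 FPKM) in NOMO1. In that line the granule genes DEFA4 and PRTN3, a protease, had trends of −6.01 ± 0.13 (7.44 ± 0.0287 against 284 ± 12.3 FPKM) and −5.45 ± 0.11 (20.8 ± 0.181 against 544 ± 47.6 FPKM). There 27 of 28 ribosomal protein genes were lower (adjusted p = 6.62e-15). In MV411, SCD fell by 4.22 ± 0.20 (7.35 ± 0.267 against 115 ± 0.29 FPKM) and KIT rose by 4.77 ± 0.17. There 30 of 30 mitosis genes were lower (adjusted p = 6.44e-24) as were 20 of 23 oxidative phosphorylation genes (adjusted p = 6.76e-10, and adjusted p = 0.169 with an estimated correlation). The DAC trend was called for 3200 higher and 3364 lower in MV411, 2914 and 1921 in THP1, and 3734 and 2496 in NOMO1. After rescaling, the DAC split was 1427 higher and 5586 lower in MV411 (median shift −0.33), 1824 and 3847 in THP1 (−0.28) and 3832 and 1629 in NOMO1 (0.15). That of GSK032 was 838 and 1924 in THP1 (−0.22).

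**Figure D3:**
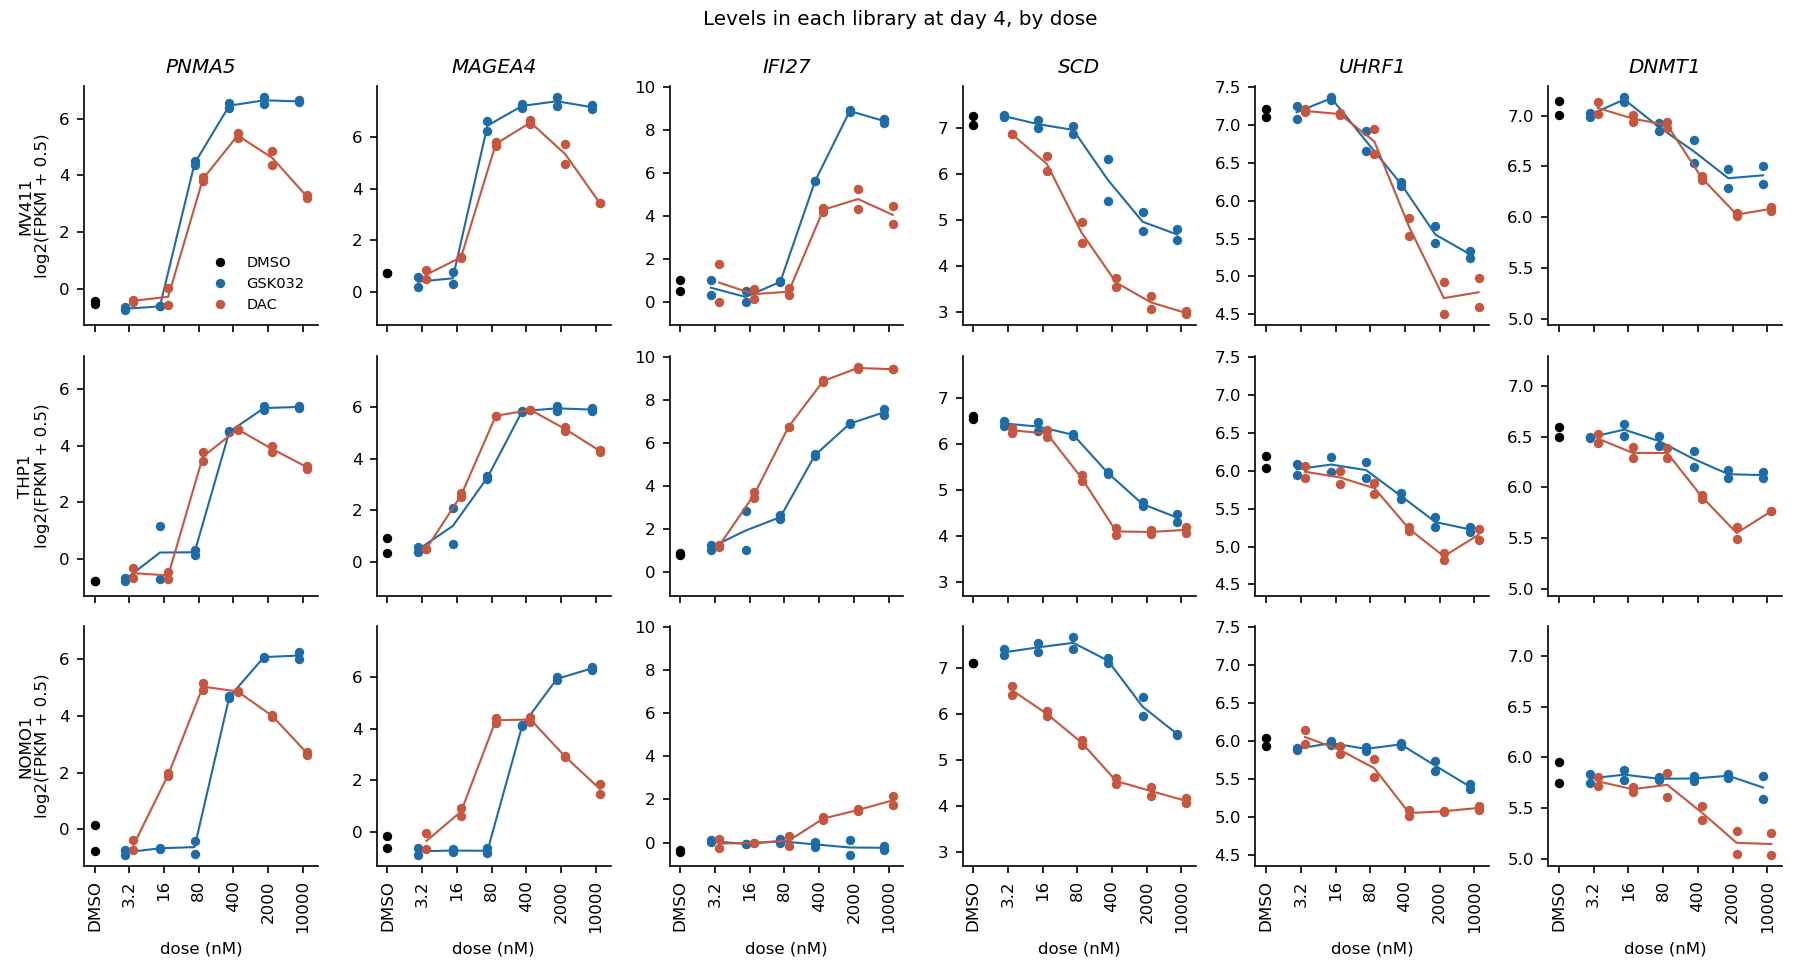
Levels of 6 genes in each day 4 library, as log2(FPKM + 0.5), by dose in nM, with DMSO in black, GSK032 in blue and DAC in red, lines through the means of 2 libraries and one row per cell line. PNMA5 with DAC was at 28.4 FPKM at 400 nM in NOMO1 and at 5.91 FPKM at 10000 nM.

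At the lowest dose, 3.2 nM, GSK032 had 0 called genes in MV411 by limma (521 of 22007 at an unadjusted p under 0.05). It had 11 without the first DMSO library, 2 without the second, and 9 without the first or without the second GSK032 library. At 80 nM it had 641 called genes in MV411, 25 in THP1 and 11 in NOMO1, against 541, 482 and 1852 with DAC. The THP1 count was 52 without the first DMSO library and 40 without the first library of 80 nM. The NOMO1 count was 22 without the first DMSO library, 3 without the second and 19 without the first library of 80 nM.

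The time course at 400 nM asked which effects grew from day 1 to day 6, as the difference from DMSO at day 6 minus that at day 1. Levels are those of day 6 against DMSO of day 6. With GSK032 in MV411, LYZ grew by 4.32 ± 0.24 (8430 ± 975 against 387 ± 30.1 FPKM) and HLA-DPA1 by 5.36 ± 0.33. Effects grew for 38 of 42 germline genes, or 39 when adjusted over the list alone (adjusted p = 1.47e-47) and 17 of 25 antigen-presentation genes, with ERAP2 lower (adjusted p = 1.43e-14). The difference between the day 6 and day 1 effects was −4.02 ± 0.27 for PHGDH. For UHRF1 this difference was −1.40 ± 0.19. In THP1, IFI27 grew by 5.70 ± 0.50 (210 ± 8.73 against 3.32 ± 0.286 FPKM) and CD14 by 2.24 ± 0.32. In NOMO1 MAGEA4 grew by 5.92 ± 0.31, CD14 by 3.19 ± 0.35, while the difference between the day 6 and day 1 effects on KIT was −2.41 ± 0.27. With DAC, IFI27 grew by 7.59 ± 0.50 (1260 ± 116 against 3.32 ± 0.286 FPKM) in THP1 with 40 of 45 interferon genes (adjusted p = 2.25e-45). In NOMO1 with DAC, MPO, the peroxidase of myeloid granules, had a difference of −5.36 ± 0.18 (36.9 ± 0.0436 against 1880 ± 126 FPKM), and the neutrophil attractant CXCL5 of 7.36 ± 0.45 (98.4 ± 36.8 against 0.0581 ± 0.00563 FPKM). There 25 of 27 NF-kB and inflammation genes were higher (adjusted p = 3.96e-14). Against DMSO of the same day, GSK032 called 380, 1442 and 1809 genes higher in MV411 on days 2, 4 and 6, and 73, 530 and 882 in NOMO1. In THP1 it called 450 on day 4 and 764 on day 6. The difference between days was called for 1629 genes higher and 921 lower with GSK032 in MV411, 634 and 136 in THP1 and 729 and 153 in NOMO1. With DAC it was called for 1178 and 675, 1404 and 585, and 2585 and 1668. Rescaling to equal sums turned the DAC splits to 657 and 622 in MV411, 790 and 771 in THP1 and 2987 and 765 in NOMO1 (median shift 0.22).

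The study's design compares its lists of changed genes, and the lists of GSK032 and DAC shared many genes. At 400 nM and day 4, 886 genes were called higher with both and 436 lower with both in MV411, where independent lists of those sizes would share 98.9 and 20.2. In THP1 the shared genes were 315 and 44, against 28 and 1.5, and in NOMO1 419 and 49, against 70 and 4.6. In NOMO1, 3 genes were called higher with GSK032 and lower with DAC (DEFA8P, RGL4 and MUC19) and 2 the other way (GZMA and SNORD114-28). GSK032 and GSK862 shared 822 higher genes in MV411 (60.5 if independent), 232 in THP1 (5.3) and 438 in NOMO1 (12.8). Both lists of a pair rest on the same 2 DMSO libraries, which were not split between them, since each list would then rest on 1 DMSO library. Simulated unchanged groups with shared controls gave 0 shared genes, which follows from their few called genes and does not show how far shared controls raise the overlap of long lists. The covariance of GSK032 and DAC fold changes was 0.47 in MV411, 0.232 in THP1 and 0.289 in NOMO1, against 0.0983, 0.0917 and 0.0883 in the simulation. Part of the overlap may come from the controls. GSK032 on day 6 and DAC on day 4 rest on different DMSO libraries. They shared 930 higher and 422 lower genes in MV411 (124.1 and 31 if independent), 532 and 83 in THP1 (47.6 and 3.5), and 649 and 95 in NOMO1 (116.4 and 12.2). The day 6 lists of GSK032 were longer than those of day 4. These overlaps thus do not show how far shared controls raise those of day 4. GSK032 and GSK477 shared 33 lower genes in MV411 (2.7 if independent), and 9 genes were higher with GSK032 and lower with GSK477. Their covariance of 0.0737 was below the simulated 0.0992. DAC and GSK477 shared 33 of the 36 genes higher with GSK477 in NOMO1 (4.8 if independent), with a covariance of 0.135 against a simulated 0.0858.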

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

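The pair of tests on fibroblast markers was chosen after the result was seen, and the other tests of this part before.

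In MV411, 98 genes were lower with GSK477 at 10000 nM on day 4, IFIT2 and CCL5 among them. One explanation is that the DMSO libraries of that day stood high for these genes. The libraries of 3.2 and 16 nM GSK032 then should have stood low against the same DMSO, but their median difference was −0.11, with 77 of the 98 genes below 0. That is 0.0751 of the difference of GSK477, which for these GSK032 libraries argues against high DMSO libraries as more than a small part of it. Low doses of DAC were not examined over the 98 genes. Against the same DMSO, DAC at 3.2 nM called 2 genes higher and 49 lower, and GSK032 at 3.2 nM called 0. Whether those 49 are among the 98 was not examined, so high DMSO libraries are not excluded for part of them. An effect of GSK477 from day 2 on needed a lower level on that day, and the median log2 difference on day 2 was −0.45, with 82 of the 98 genes below 0, which is consistent with it, beside −1.47 on day 4. Of the 98 genes, 50 were also called lower with GSK862 at day 4 (1.1 if independent), against the same DMSO. Over all genes the covariance of these compounds, 0.101, was near the 0.0982 that shared DMSO libraries gave in a simulation, so part of this overlap may come from them. The day 4 libraries of GSK862 and GSK477 are the 4 in MV411 without replicate numbers of their own. Separate handling of these 4, or a difference between cultures or lanes, stays open, since the labels give none of these.

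The split of higher and lower genes moved when every library was rescaled to the same sum. Small structural RNAs made up 55.3 to 61.5% of the sum in DMSO libraries of MV411 and 63.4 to 67.7% at 2000 and 10000 nM DAC. Leaving them out of the sums kept a median shift above 0.1 in 72.7% of the contrasts that had one (8 of 11), which lies between what was set for and against this explanation. Of these 8 shifts, 4 kept their direction and 4, all in THP1, turned to the opposite one. For GSK032 against DAC at 400 nM the shift went from 0.31 to 0.03 in MV411 and from 0.24 to 0.03 in THP1. For the DAC trend in MV411 it went from −0.33 to −0.03. In these contrasts the median shift thus came with the small RNAs in the sums, but their splits were not counted without them. Of the 19 contrasts without such a shift, 12 gained one. A change of that share by the compound was expected in all 3 lines, and the high DAC libraries lay outside the DMSO range in 2. In THP1 they were at 67.9 to 70.3% against 54.7 to 61.3%. In NOMO1 the DMSO range was 49.7 to 59.6%. There the first library of 2000 nM lay inside it, at 56.5%, and the other high DAC libraries were at 66 to 68.7%. This result too lies between its bounds, so over the contrasts and lines together both explanations stay undecided. The tests did not compare them with each other.

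Fibroblast genes rose with DAC in NOMO1, 11 of 11 measured ones with dose, of 14 in the list. RNA from fibroblasts would bring their abundant collagen and proteoglycan RNAs, but at 10000 nM the median of COL1A1, COL1A2, COL3A1, DCN and LUM was 0.0157 of the level of SPARC at most, which argues against it as the source of the whole set. COL3A1, LUM and DCN were at 0.00504, 0.94 and 1.23 FPKM beside SPARC at 85.8 ± 1.43 FPKM. COL1A1 and COL1A2 were higher, at 37.8 and 10.4 FPKM, and these levels alone exclude nothing. Fibroblast levels were assumed, since no fibroblast library was measured. The share of markers called in the dose trend, 100%, decides nothing about the dose, since this list was picked because of these same calls. The cause stays open.

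Effects at 400 nM differed between day 6 and day 1 by the test of the difference itself, for 2550 genes with GSK032 and 1853 with DAC in MV411, 770 and 1989 in THP1, and 882 and 4253 in NOMO1.

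Lists called in opposite directions in a pair of lines with the preset correlation are given as medians, and the difference between lines was not tested. Most of these calls were lost with an estimated correlation, whose adjusted p is then given. With GSK862, NF-kB and inflammation genes were at −0.39 in MV411 (adjusted p = 0.379) and 0.46 in NOMO1 (adjusted p = 0.374). With GSK477 they were at −0.62 in MV411 (adjusted p = 0.203) and 0.61 in NOMO1. Stress-response genes were at −0.18 in MV411 (adjusted p = 0.403) and 0.07 in THP1 (adjusted p = 0.628). Cholesterol and lipid genes were at −0.55 in MV411 (adjusted p = 0.199), −0.20 in THP1 (adjusted p = 0.628) and 0.17 in NOMO1 (adjusted p = 0.622). For GSK032 against DAC at 400 nM, germline genes were at 0.46 in MV411 (adjusted p = 0.0839), −1.08 in THP1 and −1.20 in NOMO1, and interferon genes at 0.48 (adjusted p = 0.0839), −1.27 and −0.46.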

How the results depend on the processing

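The GSK032 day 6 overlap was planned, and leaving out both doubtful THP1 libraries was chosen after the result was seen. Of the counts of called genes in the main comparisons, those not named here stayed within 1.5 times the reported count under each pseudocount, without the filter, after rescaling to equal sums and with a replicate block. Of 2170 gene results, 2146 kept direction and call without the filter, 2132 with a pseudocount of 0.1, 2052 with a pseudocount of 1 and 1988 after rescaling, where 152 lost the call. Of 864 list results, 779 kept both after rescaling and 570 with an estimated correlation, where 294 lost the call. The replicate block kept 2037 gene results and has no value for GSK862 and GSK477 at day 4 in MV411, whose libraries lack numbers.

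With a pseudocount of 1, the total was 69 for GSK477 in MV411 (105 reported), and in THP1 342 for GSK032 (528), 190 for GSK862 (304), 5 for GSK477 (9) and 511 for the GSK032 difference between days (770). With a pseudocount of 0.1, THP1 had 890 for GSK032, 560 for GSK862 and 1585 for GSK032 against DAC (1052), and NOMO1 had 1007 for GSK032 (608), 1029 for GSK862 (598) and 69 for GSK477 (44). A larger pseudocount shrinks changes of genes near 0 by construction, and a smaller one widens them. After rescaling, THP1 had 190 for GSK862, 4 for GSK477 and 472 for the GSK032 difference between days, and NOMO1 had 24 for GSK477. The overlap of GSK032 on day 6 with DAC on day 4 held 615 genes in THP1 and 744 in NOMO1, against 359 and 468 for GSK032 and DAC both on day 4. GSK032 also called more genes on day 6 than on day 4, 947 against 528 in THP1 and 1087 against 608 in NOMO1. The larger overlap is therefore not a measure of shared controls. Leaving out 1 library gave 12 to 36 genes for GSK477 in THP1 and 18 to 99 in NOMO1. Rescaling reversed the lists of ribosomal proteins in MV411 (adjusted p = 0.00265) and oxidative phosphorylation in THP1 (adjusted p = 0.0408), both for GSK032 against DAC at 400 nM. Where not stated, the cause was not tested. Without counts, the limit that depth sets on genes near 0 is unknown.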

Other observations

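The contrasts of 10000 nM with 400 nM in this part were chosen after the result was seen, and the authors' fold changes were compared as planned.

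PNMA5 and some germline genes were lower at 10000 nM of DAC than at 400 nM. From 400 to 10000 nM of DAC at day 4, MAGEA4 changed by −3.15 ± 0.23 (10.3 ± 0.00324 against 94.9 ± 7.42 FPKM) in MV411, −1.60 ± 0.23 (19.2 ± 0.628 against 59.1 ± 0.503 FPKM) in THP1 and −2.70 ± 0.22 (2.7 ± 0.612 against 20.2 ± 1.6 FPKM) in NOMO1, and PNMA5 by −2.16 ± 0.20, −1.33 ± 0.29 and −2.17 ± 0.21. The germline list was lower at 10000 nM in MV411, with 29 of 42 called (adjusted p = 9.1e-21), and in NOMO1, with 17 of 36 lower and XAGE1B higher (adjusted p = 1.73e-11), and did not pass in THP1 (adjusted p = 0.168). With GSK032 the same list was higher at 10000 nM, with 11 of 42 called in MV411 (adjusted p = 1.24e-20), 20 of 34 in THP1 (adjusted p = 6.4e-35) and 28 of 36 in NOMO1 (adjusted p = 3.96e-26), and DAZL in NOMO1 went from 0.113 to 42.5 FPKM. The difference between the compounds in this step was not tested.

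Some lists of other tissues were higher over the same range of DAC, and some did not pass. Fibroblast genes were higher at 10000 than at 400 nM in MV411, with 5 of 9 called (adjusted p = 2.83e-06), and in THP1, with 8 of 10 (adjusted p = 5.45e-13). In THP1 the PDGFRA call ended without the first library of 10000 nM, at 0.86, and DCN was called without the second of 400 nM, at 1.08. In NOMO1 COL1A1, COL6A3, PDGFRA, THY1 and SPARC of 11 were called (adjusted p = 0.00464, and adjusted p = 0.0997 with an estimated correlation), while COL1A2 went from 19.6 to 10.4 FPKM and FBLN1 from 22.5 to 17.9 FPKM. Epithelial genes were higher in THP1, with 6 of 8 (adjusted p = 3.44e-08), and NOMO1, with 6 of 12 (adjusted p = 2.93e-07), and did not pass in MV411 (adjusted p = 0.2). In THP1 the CLDN4 call ended without the second library of 400 nM, at 0.9, or of 10000 nM, at 0.84. In NOMO1 the calls of CLDN7 and ELF3 ended without the second library of 10000 nM, at 0.97 and 0.79, and that of ELF3 without the first of 400 nM, at 0.66, while KRT19 was called without the second of 400 nM, at 1.09. T-cell genes were higher in NOMO1, with TRAC, TRBC2 and GZMB of 10 called (adjusted p = 0.00265), while the other 7 ran from −0.9 ± 0.15 (CD5) to 1 ± 0.12 (CD7) and were not called. The TRAC call ended without the second library of 400 nM, at 0.92, and CD5 was called lower without the first of 10000 nM, at −1. CD7 was called higher without the first library of 400 nM, at 1.08, or of 10000 nM, at 1.04, and CD8A without the second of 400 nM, at 1.1. T-cell genes were also higher in THP1, with TRAC called (adjusted p = 0.00589, and adjusted p = 0.0502 with an estimated correlation), and CD3D too without the first library of 10000 nM, at 1.4, or the second of 400 nM, at 1.34. They did not pass in MV411 (adjusted p = 0.139). With GSK032, interferon genes rose further from 400 to 10000 nM in MV411, with 35 of 45 called (adjusted p = 7.85e-74), and NF-kB and inflammation genes in NOMO1, with 24 of 27 (adjusted p = 1.46e-28). In all, this step called 329 genes higher and 154 lower with GSK032 in MV411, 344 and 70 in THP1, and 1042 and 239 in NOMO1, and with DAC 585 and 669, 661 and 258, and 627 and 450. Rescaling to equal sums moved the median gene by −0.26 with DAC in MV411 and turned its split to 143 higher and 2130 lower. The MV411 total with DAC, 1254, was 2170 without the first library of 10000 nM.

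The log2 fold changes in the authors' deposited tables were compared with the limma estimates over genes with an FPKM of at least 3 in every library of a line. These were 9689 genes in MV411, 10318 in THP1 and 9801 in NOMO1. Genes near 0 in DMSO, such as PNMA5 and MAGEA4, were thus not compared. The correlation across genes, which are not independent replicates, exceeded 0.9 in 22 of 24 columns in MV411, 20 of 24 in THP1 and 24 of 24 in NOMO1, with values up to 0.999. Columns for 400 nM at day 4 stand in both the time and the dose part with identical values, for GSK032 in each line and for DAC in MV411 and NOMO1, so these comparisons count double. An MV411 column headed 200 nM DAC, a dose that no library has, was taken as 2000 nM (r = 0.999). Columns of different lines were compared by row position, not by gene. In the MV411 table the values for 400 nM DAC at day 1 equalled those of the NOMO1 table in 47210 of 47210 rows (r = 0.001 with the MV411 libraries). Those for GSK477 at day 4 equalled those of the THP1 table in 46382 of 46382 rows (r = −0.002). The MV411, NOMO1 and THP1 tables have 47210, 47360 and 46382 rows, so a row need not hold the same gene in each. In the THP1 table the values for 10000 nM DAC at day 4 had r = 0.002, and those for 400 nM DAC in the dose part repeated the day 6 values (r = 0.839 with day 4). The THP1 values for 16 and 80 nM GSK032 had r = 0.777 and 0.853. Against single libraries these were 0.310 and 0.890 for 16 nM, and 0.401 and 0.941 for 80 nM, numbered 1 and 2.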
